A study of Rattus norvegicus with 10 samples.

How the data were processed

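Mononuclear cells of arterial and venous blood of 5 healthy rats were measured by single-cell RNA sequencing in 10 libraries, 5 per vessel. Per the labels' protocols, blood was drawn from the abdominal aorta and the inferior vena cava under isoflurane, and libraries were made with 10x Chromium 3' version 3 reagents and sequenced on a DNBSEQ-T7. The deposited values are raw counts of UMIs per gene and cell barcode, which the authors made with Cell Ranger 8.0.0, per the file headers; the submitters' processing notes name Cell Ranger too. The genome build, annotation and settings are not given in the sources used here. Each matrix held 25629 genes, of which 3852 carried an identifier in place of a symbol, and 211 symbols were shared by more than 1 identifier. No symbol was found for the 3852 through the reference table of gene names. A symbol shared by several genes is printed with no identifier where the text calls it "a gene" of that name.

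The vessel was taken from the labels and the number of the rat from the library titles, and the study's design states that the samples are paired. The comparisons, their tests, the cell type markers, the rule for naming genes, 27 gene lists and most alternatives were fixed before the data were examined. The pairing was checked on the sums of all cells: deviations from the vessel means of libraries with the same number correlated at 0.854 to 0.942 over genes, against at most 0.653 to 0.817 with any other library of the other vessel, and within rats 1 to 3 at 0.584 to 0.689 against at most -0.184. Genes are not independent replicates in these correlations. No pair of libraries was a duplicate: the lowest chi-square per degree of freedom over the 45 pairs of libraries was 34.9.

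Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were left out. Barcodes with few genes numbered 1873 ± 2161 (SD, n = 5) per arterial and 1574 ± 2137 per venous library, most of them in rats 4 and 5. Doublets were called per library by comparing each cell with simulated sums of 2 cells in principal component space. Library minima of the score set the threshold in the usual way, but that of arterial library 4 was far lower, at 0.103, than the others. After this was seen, the median of the library minima, 0.289, was used for all. Doublet calls made up 9.90% ± 4.21 of arterial and 8.78% ± 2.30 of venous cells and were removed. Sums of 2 like cells are rarely recognised by this method.

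Kept cells were scaled to one total, log transformed, scaled within each rat on 2000 variable genes, reduced to 30 principal components, corrected for the rat with a Harmony-like procedure, linked to 20 neighbours and clustered with Leiden at a resolution of 1. A first clustering without that correction had split by batch and was replaced. The 31 clusters were named from the fixed markers: a marker counted when it was seen in at least 20% of the cells and raised at least 1.5-fold over other clusters, and at least 3 had to count. Clusters with markers of 2 lineages stayed unnamed. The part of that rule about platelet genes was rewritten after it had left a classical monocyte cluster unnamed. The unnamed clusters held 5.75% ± 2.06 of arterial and 4.15% ± 1.06 of venous cells (log2 fold change 0.43 ± 0.32). T-like clusters were split by Foxp3 and by Cd8b because Cd4 was not among the symbols used here; Cd8b-low T-like cells therefore stand in for CD4 T cells without being shown to be them. No deposited annotation of the cells was used here, so shares depend on these rebuilt names.

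Shares of classes and clusters were compared with edgeR's quasi-likelihood test on the number of cells, offset by the cells kept, with the rat as a block. Genes were compared with edgeR's quasi-likelihood test on UMI counts summed per library and class, with TMM factors, filterByExpr and the rat as a block, in libraries with at least 20 cells of the class and at least 3 pairs. Adjusted p-values are Benjamini-Hochberg over the classes, the clusters or the genes of a class, with a threshold of 0.05, and a log2 fold change is always arterial over venous with its standard error. Gene lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 277 tests. Ratios and library values, and class shares beside edgeR's test, were compared with an exact two-sided sign-flip permutation test of the 5 paired differences, which cannot give a p under 0.063. Class-dependent effects were tested as an interaction on the sums of 2 classes with the library as a block. CPM are the summed UMI counts scaled to a fixed total. The number of cells in a sum limits its precision: sums held between 72 and 890 cells per library in classical monocyte-like cells and between 2482 and 7116 in Cd8b-low T-like cells.

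Named genes are the 10 largest rises and the 10 largest falls in all cells, and the 5 largest of each in every class, among genes past the threshold that changed the same way in all pairs; where none passed, the 5 lowest p-values were taken as values only. Members of the fixed lists that passed, or whose list passed, could be named too. One of the genes so picked in all cells is not reported here. Gene models without a symbol were passed over, 75 of the 982 calls in all cells among them. Platelet, haemoglobin, neutrophil and vessel wall genes were among the lists, as markers of cells that the preparation could carry; of 7 vessel wall and abdominal tissue genes tested in all cells none passed (median log2 fold change -0.10), and of 14 neutrophil genes none passed (median 0.07).

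The tests were tried on simulated counts with 200 changed genes, drawn from the real means and library sizes. In B-like cells, with the spread of single genes, 95% of genes planted with a log2 fold of 1 and 65% of those with 0.5 were called, and 9.61% of the calls were false; with the trended spread these were 94%, 72% and 6.22%. In classical monocyte-like cells false calls made up 13.3% and 4.58% of the calls, more in the first case than the threshold of 0.05 states. In 100 simulated tables of 12 classes, a 1.5-fold change of a share was found in 34.5% of cases, and 15.9% of calls were false. Of 40 unchanged lists in simulated B-like cells camera called 0, and it called the planted one. The simulated genes were drawn independently, so this cannot show how camera behaves on lists of correlated genes. In the real data, with the vessels of some rats exchanged, between 12 and 39 list tests still passed camera, against 45 for the real vessels.

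Alternatives were no rat block, DESeq2's size factors and Wald test, no filter on low counts, sums thinned to one total, doublet calls kept, a stricter cell filter of 500 genes and 5% mitochondrial UMIs, resolutions of 0.5 and 2, other denominators, a library size without haemoglobin, platelet, neutrophil and immunoglobulin genes, limma on shares and leaving out each rat. Comparisons within rats 1 to 3 and within rats 4 and 5, split at a mean mitochondrial share of 2.5%, removal of genes at least 4-fold enriched in the platelet-like cluster, erythroid barcodes counted over all deposited barcodes, and class-by-rat blocks for the interaction were added after seeing the data. Trial fits of shares and genes were run before the simulations and before some of the later tests were written down. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.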

Results

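Single-cell RNA sequencing was used to compare mononuclear cells of arterial blood, taken from the abdominal aorta, with those of venous blood, taken from the inferior vena cava, in 5 healthy rats. Each rat gave 1 library per vessel, so that 5 arterial and 5 venous libraries formed 5 pairs. The files held between 13267 and 24338 barcodes per library and between 69682700 and 133320477 unique molecular identifiers (UMIs). After filtering and removal of doublet calls, 139273 cells remained, between 12068 and 15897 per library. The median UMI count per kept cell was 4746 ± 291 (SD, n = 5) in arterial and 4283 ± 436 (SD, n = 5) in venous libraries, and was higher in the arterial library in 5 of 5 pairs (exact two-sided sign-flip permutation test, p = 0.063, the smallest p that 5 pairs allow). When each cell outside the erythroid-like and platelet-like classes was thinned to 2000 UMIs, the median number of genes per cell was 1102 ± 84.0 in arterial and 1109 ± 83.0 in venous libraries, against 1952 ± 199 and 1835 ± 200 without thinning in the same classes. Cells under 2000 UMIs, which this comparison left out, made up 2.47% ± 0.924 of arterial and 3.85% ± 1.30 of venous cells of these classes.

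The rats fell into 2 sets that the vessel did not explain. The median mitochondrial share of UMIs per kept cell lay between 4.74% and 5.27% in the 6 libraries of rats 1 to 3 and between 0.872% and 1.02% in the 4 libraries of rats 4 and 5. Both libraries of a rat always fell in the same set, so the comparison of vessels could be made within each. Haemoglobin genes took 11.7% ± 11.2 (SD, n = 5) of all UMIs in arterial and 9.55% ± 11.03 in venous libraries, with the higher share in the arterial library in 5 of 5 pairs (exact sign-flip permutation p = 0.063).

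The first comparison asked how the makeup of the mononuclear cells differed between the vessels. Platelet-like barcodes, defined by Pf4, Gp9, Treml1 and Clec1b, made up 1.37% ± 0.491 (SD, n = 5) of arterial and 0.523% ± 0.104 of venous cells. Erythroid-like barcodes, rich in haemoglobin transcripts, made up 5.34% ± 7.04 and 2.61% ± 3.74, with rat 4 highest at 17.4% and 9.17%. Natural killer (NK)-like cells, with the granzyme genes Gzma and Gzmb and the receptor gene Klri1, were less frequent in arterial blood at 3.11% ± 1.19 against 4.87% ± 1.46. Non-classical monocyte-like cells, marked by Adgre4, Fcgr3a and Csf1r, were also less frequent at 6.97% ± 3.18 against 10.2% ± 4.56. Each of these differences had the same direction in 5 of 5 pairs. The erythroid-like share leaves out clusters 14 and 21, which mixed erythroid with T or B markers and stayed unnamed. They had log2 fold changes of -0.53 ± 0.50 and -0.82 ± 0.33 (SE, edgeR adjusted p = 0.432 and 0.109). With them counted in, the share was no longer higher in the arterial library of rats 1 and 5.

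By edgeR's quasi-likelihood test with the rat as a block, the log2 fold change (arterial over venous) was 1.34 ± 0.20 (SE) for platelet-like barcodes (adjusted p = 0.00941) and 1.17 ± 0.23 for erythroid-like barcodes (adjusted p = 0.0166). It was -0.67 ± 0.17 for NK-like cells (adjusted p = 0.0297) and -0.53 ± 0.13 for non-classical monocyte-like cells (adjusted p = 0.0297). Within rats 1 to 3 and within rats 4 and 5 the values were 1.59 and 0.95 for platelet-like, 1.43 and 0.86 for erythroid-like, -0.91 and -0.30 for NK-like and -0.66 and -0.35 for non-classical monocyte-like cells. The NK-like call was lost without rat 1, 2, 3 or 4, the non-classical monocyte-like call without rat 2, 3 or 4, and the erythroid-like call without rat 4. The 3 calls were also lost with no rat block and with a stricter cell filter, and the platelet-like call under the stricter filter alone of these. Under that filter the values were -0.45 for NK-like, -0.23 for non-classical monocyte-like, 0.26 for erythroid-like and 1.04 for platelet-like cells. TMM factors over the counts of cells ended the NK-like and non-classical monocyte-like calls, and a resolution of 0.5, with clusters named anew, the NK-like and erythroid-like calls. The planned exact sign-flip permutation test of the shares gave p = 0.063 for each of the 4 classes, the smallest that 5 pairs allow. Adjusted over the classes this was 0.135, and none passed. B-like and Cd8b-high T-like cells had the same p and adjusted p by that test.

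B-like cells made up 21.7% ± 11.1 (SD, n = 5) of arterial and 27.2% ± 11.2 of venous cells and were less frequent in the arterial library in 5 of 5 pairs. Their log2 fold change of -0.41 ± 0.13 did not pass the test (edgeR, adjusted p = 0.0528), with -0.23 within rats 1 to 3 and -0.70 within rats 4 and 5. T-like cells with low Cd8b made up 31.7% ± 9.96 and 28.1% ± 10.6, and those with high Cd8b, a chain of the CD8 co-receptor, 15.7% ± 4.21 and 14.01% ± 4.42. Their log2 fold changes of 0.20 ± 0.11 and 0.17 ± 0.09 did not pass the test (edgeR, adjusted p = 0.217 for both). The Cd8b-low share was higher in the arterial library in 4 of 5 pairs and the Cd8b-high share in 5 of 5. Regulatory T-like cells with Foxp3, the transcription factor that defines this lineage, stood at 4.20% ± 0.693 and 3.97% ± 0.396 (log2 fold change 0.07 ± 0.09, edgeR adjusted p = 0.593). This class was 1 cluster of 5674 cells. At a resolution of 2 a cluster of 2361 cells led by Foxp3 kept the name. Another of 3349 cells, led by Maf, Rora and Icos, was named Cd8b-low T-like, so the name depended on the resolution. Classical monocyte-like cells stood at 3.35% ± 2.70 and 3.41% ± 2.84 (log2 fold change 0.13 ± 0.19, edgeR adjusted p = 0.593). Plasmacytoid dendritic-like, neutrophil-like and proliferating cells each made up under 1% of cells on average in either vessel, and none of the 3 passed the test.

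**Figure D1:**
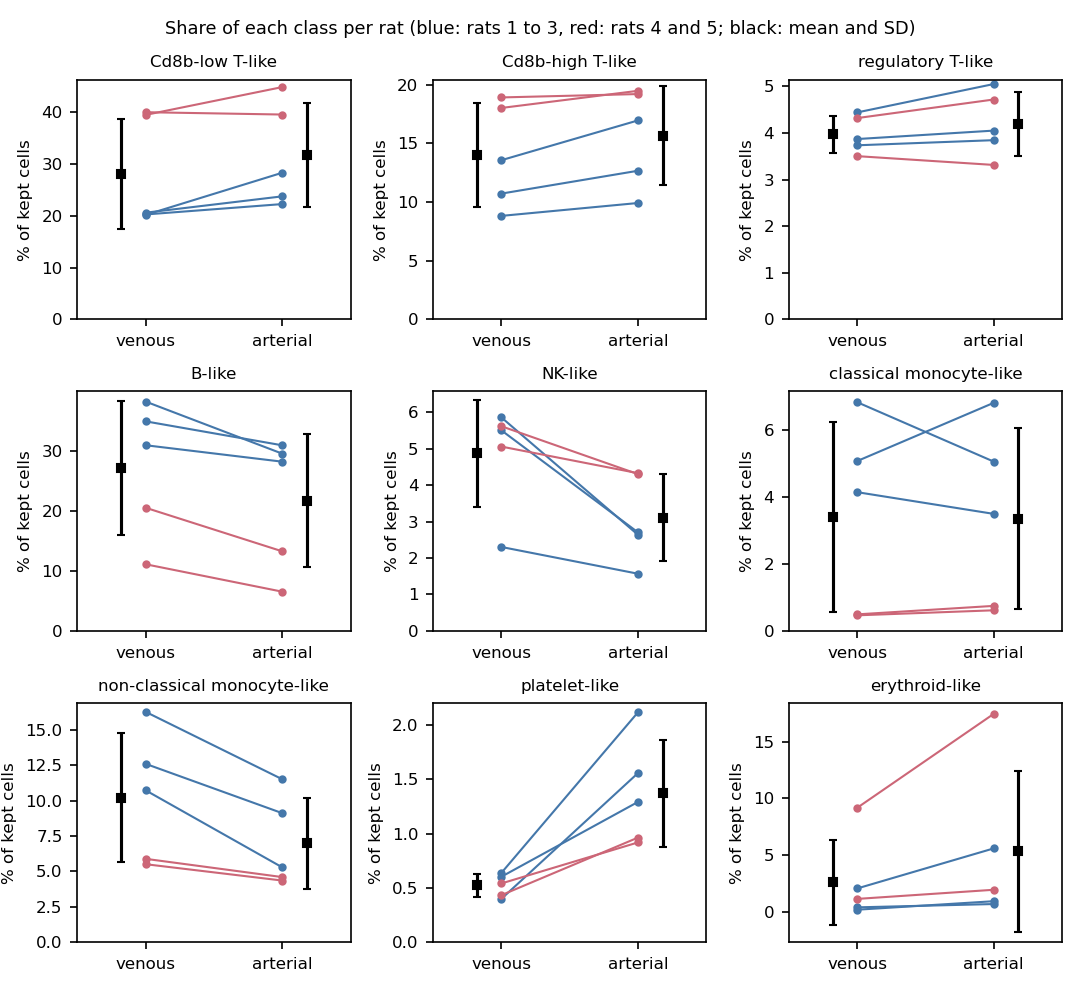
Percent of kept cells in each of 9 classes per library (y axis), venous at the left and arterial at the right of each panel; lines join the libraries of a rat (blue, rats 1 to 3; red, rats 4 and 5) and black squares give the mean and SD of the 5 libraries. The lines of platelet-like and erythroid-like barcodes rise and those of NK-like and non-classical monocyte-like cells fall from venous to arterial in 5 of 5 rats.

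Ratios of cells, which do not depend on the denominator of the shares, were also taken per pair. The ratio of T-like to B-like cells was higher in arterial blood in 5 of 5 pairs, with a mean log2 difference of 0.59 ± 0.20 (SD, n = 5). The ratio of classical to non-classical monocyte-like cells was higher by 0.68 ± 0.38, and that of lymphocytes to monocytes by 0.36 ± 0.30, both in 5 of 5 pairs. Under the stricter cell filter the last of these was 0.07. For each of these 3 ratios the exact two-sided sign-flip permutation p was 0.063, the smallest that 5 pairs allow (n = 5). The ratio of Cd8b-low and regulatory T-like cells together to Cd8b-high T-like cells differed by 0.01 ± 0.09. It was higher in 3 of 5 pairs (exact sign-flip permutation p = 0.875). Among 31 clusters compared by number, 2 passed the test: the NK-like cluster 11, led by Gzma, Gzmb and Ccl5, at -0.85 ± 0.17 (edgeR, adjusted p = 0.0324), and the platelet-like cluster 16 (edgeR, adjusted p = 0.0193). The other NK-like cluster, 12, led by the haemoglobin gene Hbe1 and with Xcl1 and Klrb1b among its leading genes, had a log2 fold change of -0.38 ± 0.26. It did not pass (edgeR, adjusted p = 0.288). No cluster passed without rat 1 or without rat 5, and 1 passed with no rat block.

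Genes were first compared in the sums of all kept cells, which mix composition with expression. Of 14742 genes tested, 538 were higher and 444 lower in arterial blood (edgeR's quasi-likelihood test with the rat as a block, threshold 0.05 on the adjusted p). The balance of directions depended on the library size: with haemoglobin, platelet, neutrophil and immunoglobulin genes left out of it, 410 were higher and 608 lower. Among the largest rises in all 5 pairs was Mgp, which codes for an inhibitor of calcification (log2 fold change 2.78 ± 0.65 SE, edgeR adjusted p = 0.0446). Others were Lif, a cytokine (2.25 ± 0.25, edgeR adjusted p = 0.0115), and Ptgs2, the inducible cyclooxygenase (1.72 ± 0.24, edgeR adjusted p = 0.0155). The neutrophil-attracting chemokines Cxcl3 (1.47 ± 0.18) and Cxcl2 (1.15 ± 0.13) were also among them. So were Fgf18 (1.31), Sytl4 (1.28), Als2cl (1.16), Socs1, a feedback inhibitor of cytokine signalling (1.10), and Nos2, the inducible nitric oxide synthase (1.0). Large falls were in Zfp366 (-1.43), in the NK receptor genes Kir3dl1 (-1.0) and Ncr1 (-0.71), and in Sh3gl2, Kcnj1, Qrfpr, Cd209d, Try10 and Sgca (between -0.79 and -0.74). Mgp, Lif, Fgf18, Sytl4, Als2cl, Zfp366, Kir3dl1, Kcnj1, Cd209d and Try10 had under 1 CPM (UMI counts scaled to a fixed total) on average in at least one vessel, so their folds rest on few molecules. Carry-over from the vessel wall was examined only through the gene list given above, and is not excluded as a source of Mgp.

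By list, 8 of 9 haemoglobin and erythroid genes were higher in the sums of all cells, Hba-a1 by 0.93 and Alas2, the first enzyme of haem synthesis in red cells, by 0.86. Of 11 platelet genes, 6 were higher, among them Clec1b (0.90) and Pf4 (0.81). Of 13 genes of T cell activation, 6 were higher, including Il2ra (0.62), Havcr2 (0.79) and Ctla4 (0.40), and Cd38 was lower (-0.24). MHC class II genes had 3 of 13 lower, namely the class II transactivator Ciita (-0.43), RT1-DOa and Ifi30. No list was tested as a whole in these sums, in which the makeup of the cells also enters. With no rat block edgeR called 0 genes (248 at an unadjusted p under 0.05), rats 4 and 5 alone gave 0 (1312 unadjusted), and leaving out rat 1, 2, 3, 4 or 5 gave 159, 21, 202, 505 and 1272.

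The next comparison asked which genes differed within a class of cells. The order and time of the draws are not given in the labels. In every class, a difference in handling between the draws therefore cannot be told apart from the vessel. In Cd8b-low T-like cells, the most numerous class with 42760 cells, 260 genes were higher and 50 lower in arterial blood of 11466 tested (edgeR). Socs1 rose by 1.27 ± 0.08 (SE, adjusted p = 0.000155), Trem1, a receptor that amplifies inflammatory responses, by 1.23 ± 0.10 (adjusted p = 0.000640), the phosphatase gene Dusp8 by 1.47, Trem3 by 1.24 and Gadd45g by 1.24. Immediate early genes were higher in 5 cases, including the nuclear receptors Nr4a2 (0.83 ± 0.10) and Nr4a3 (0.75 ± 0.15) and the early activation antigen Cd69 (0.29 ± 0.05). Il2ra, the alpha chain of the interleukin-2 receptor, rose by 0.56 ± 0.07, and Sgk1, a kinase gene induced by glucocorticoids, by 0.63 ± 0.08. The largest falls were in 4 replication-linked histone H2A and H4 genes (between -0.55 and -0.49) and Tmem204 (-0.40); near-identical copies of such histone genes can share reads. The main clusters of this class did not shift alike: cluster 0 made up 23.1% ± 8.93 (SD, n = 5) of arterial and 17.1% ± 8.14 of venous cells and cluster 3 7.77% ± 1.24 and 10.3% ± 2.91 (edgeR, adjusted p = 0.0736 and 0.109), so the values may carry part of that shift.

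In Cd8b-high T-like cells, 131 genes were higher and 39 lower of 11358 tested (edgeR). Here the falls held the larger known effectors. Ccl5, a chemokine stored by effector T cells, fell by 0.81 ± 0.10 (SE, adjusted p = 0.00428) from 669 to 363 CPM, and Zeb2, a transcription factor of terminally differentiated effector cells, fell by 0.90 ± 0.16 (adjusted p = 0.0267). The venous mean of Ccl5 was raised by rat 2, at 10.71 log2 CPM against 8.33 to 8.98 in the other venous libraries, but the fall was seen in 5 of 5 pairs. Of 16 cytotoxic effector genes, 4 were lower and none higher, namely Ccl5, Nkg7 (-0.34), Cst7 (-0.40) and the granzyme gene Gzmm (-0.26); adjusted over the list alone the count was also 4. Cluster 20 of this class, led by Ccl5, Gzmm and Gzmk, was less frequent in the arterial library in 5 of 5 pairs (-0.48 ± 0.14, edgeR adjusted p = 0.0538), so these falls may carry part of a shift within the class. This list passed camera (adjusted p = 0.0107; adjusted p = 0.70 with an estimated correlation). The largest rises were in Fgf18 (1.77), Trem1 (1.10), the platelet gene Clec1b (1.09), Metrnl (0.99) and Pla2g2a (0.99), another leading gene of the platelet-like cluster. In regulatory T-like cells, 79 genes were higher and 14 lower of 9431 in this cluster. At the top were Myl9 (1.07), Socs1 (0.98), Socs3 (0.95), the prostaglandin receptor gene Ptger2 (0.88) and Fhl2 (0.76), of which Myl9 is a leading gene of the platelet-like cluster. Pcp4 (-1.30) and St3gal3 (-0.79) fell most.

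Of 11529 genes tested in B-like cells, 445 were higher and 109 lower (edgeR). Of 21 immediate early genes 11 were higher and none lower, and 16 adjusted over the list alone. Dusp2 rose by 1.13 ± 0.11 (SE, adjusted p = 0.000601), Nr4a2 by 1.07 ± 0.18, Nr4a1 by 0.83 ± 0.10, Fos by 0.67 ± 0.10 and Egr1 by 0.53 ± 0.11. The list passed camera (adjusted p = 1e-06; adjusted p = 0.70 with an estimated correlation). Of 13 circadian clock genes, 5 were higher, Ciart by 0.60 ± 0.07, Nr1d2 by 0.50 ± 0.08, Bhlhe40 by 0.49 ± 0.07, Cry2 by 0.39 ± 0.07 and Cry1 by 0.20 ± 0.05, with 6 adjusted over the list alone (camera adjusted p = 0.00691; adjusted p = 0.70 with an estimated correlation). The chemokine receptor genes Cxcr5 (0.44), Ackr3 (0.45) and Cxcr4 (0.32) were higher too, as was Il7r (0.66), for which RNA or cells of the T lineage are not excluded either. The largest single rises were in Gucy1b1, a subunit of soluble guanylate cyclase (1.33), Muc20 (1.32), Slc40a1, the iron exporter ferroportin (1.24), Ica1 (1.22) and Alox12, the platelet-type lipoxygenase (1.20), and the largest falls in Osbpl10 (-0.75) and Sh3gl2 (-0.53). Platelet genes also rose in this class, as given below, so RNA of platelets is not excluded as a source of these rises. Without genes at least 4-fold enriched in the platelet-like cluster, 510 genes were called in B-like cells, 496 of them among the 554 of the main fit.

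In NK-like cells, 70 genes were higher and 11 lower of 9964 tested (edgeR). Cxcr4, the receptor that holds leukocytes in bone marrow, rose by 0.66 ± 0.07 (SE, adjusted p = 0.00120), Il7r by 0.94 ± 0.17 and Foxo1, a regulator of homing genes, by 0.47 ± 0.07. These were 3 of 12 genes of lymphocyte egress and homing, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000227; adjusted p = 0.70 with an estimated correlation). Cd83 (0.92), Birc3 (0.64), Relb (0.53) and Nfkbia (0.34) rose among 11 genes of the NF-kB list (camera adjusted p = 0.00239; adjusted p = 0.70 with an estimated correlation), with 7 higher and 2 lower adjusted over the list alone. Large rises were also in Dach2 (1.67), Trib2 (1.36), Mid2 (1.13) and Adam19 (1.01). Dach2, Adam19 and Il7r are also leading genes of the T-like cluster 0, so RNA or cells of the T lineage among the NK-like cells are not excluded for them. Zeb2 fell by 0.50 ± 0.07, and Zfp821, Rab27b, which serves granule release, Spink2 and a Slfn4 gene by between 0.68 and 0.46 on the log2 scale. Of the NK-like clusters, 11 held more of the venous and less of the arterial cells, as given above, so these values may also carry part of that shift.

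Non-classical monocyte-like cells had 101 genes higher and 13 lower of 9701 tested (edgeR). Ptgs2 rose by 1.83 ± 0.22 (SE, adjusted p = 0.000619), Ebf1 by 1.20 ± 0.18, Dusp2 by 1.08 ± 0.18, Thbd, the anticoagulant thrombomodulin, by 1.04 ± 0.11 and Nos2 by 0.99 ± 0.18. Ebf1 is a leading gene of the B-like clusters, and RNA or cells of that lineage are not excluded as its source. Of 18 hypoxia-inducible factor targets, Pfkfb3 (0.60), Mxi1 (0.43) and Ndrg1 (0.29) were higher and none was lower, with 5 higher adjusted over the list alone (camera adjusted p = 0.00277; adjusted p = 0.70 with an estimated correlation). Il1b (0.52) and Cxcl2 (0.56) rose as well. Ccl5 fell by 0.78 ± 0.14, and the 4 other named falls, Etfbkmt, Scarb1, Dusp6 and Rmdn1, lay between -0.46 and -0.31.

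Classical monocyte-like cells had 274 genes higher and 72 lower of 9994 tested (edgeR), and the NF-kB inflammatory list stood out. Of its 20 measured members 13 were higher and none lower, and 17 adjusted over the list alone. Cxcl2 rose by 1.30 ± 0.08 (SE, adjusted p = 3.06e-07) from 203 to 504 CPM, Cxcl1 by 1.60 ± 0.09, Ptgs2 by 1.99 ± 0.15, Birc3, an inhibitor of apoptosis, by 1.22 ± 0.10, Tnf by 0.93 ± 0.12, Nfkbia, the NF-kB inhibitor, by 0.84 ± 0.09, Ccl2 by 0.84 ± 0.10 and Il1b by 0.66 ± 0.09. Ptgs2, Cxcl1 and Tnf were higher in 4 of 5 pairs and the others just named in 5 of 5. The list passed camera (adjusted p = 1.77e-11; adjusted p = 0.70 with an estimated correlation). Immediate early genes had 6 of 21 higher, among them Dusp2 (1.79), Ier3 (1.5) and Nr4a2 (1.04), with 11 adjusted over the list alone (camera adjusted p = 2.52e-05; adjusted p = 0.70 with an estimated correlation). Vegfa, a hypoxia target, rose by 1.81 ± 0.26, Pfkfb3 by 0.71 ± 0.08 and Hk1 by 0.60 ± 0.11, while the heat shock gene Hspa1b fell by 1.54 ± 0.18 and Ikzf1 by 0.64 ± 0.12. Cxcl3 (1.60), Maff (1.47), Cdca2 (1.30) and the NK gene Klrd1 (1.61) rose as well, and Dnah14 (-1.33) fell. Rats 4 and 5 gave few of these cells, between 72 and 119 per library against 426 to 890 in rats 1 to 3, and sums thinned to one total left 44 genes called in place of 346.

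**Figure D2:**
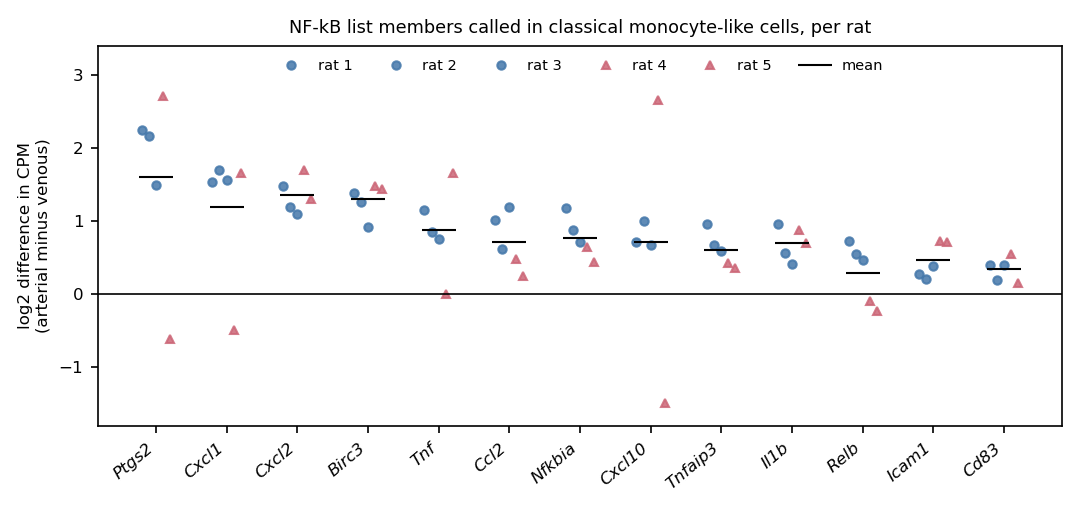
Difference in log2 CPM between the arterial and the venous library of each rat (y axis) for the 13 NF-kB list members called in classical monocyte-like cells (x axis); circles are rats 1 to 3, triangles rats 4 and 5, and black dashes the mean of the 5. All points of rats 1 to 3 lie above 0, while rat 4 has values below 0 for Cxcl1 (-0.49) and Relb (-0.09) and 0 for Tnf, and rat 5 has values below 0 for Ptgs2 (-0.62), Relb (-0.23) and Cxcl10 (-1.49).

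Some genes of platelets were also higher in arterial blood within other classes: 3 of 6 tested passed in Cd8b-low T-like, 3 of 8 in Cd8b-high T-like, 2 of 5 in regulatory T-like, 4 of 7 in B-like, 1 of 6 in NK-like, 3 of 6 in non-classical monocyte-like and 2 of 4 in erythroid-like cells (edgeR). Clusters that joined platelet markers with those of T or B cells had stayed unnamed and are not in these classes. Cluster 10, with T markers, made up 3.54% ± 1.28 (SD, n = 5) of arterial and 1.49% ± 0.484 of venous cells and was higher in 5 of 5 pairs. Cluster 19, with B markers, made up 0.872% ± 0.721 and 0.426% ± 0.320 and was higher in 4 of 5. Neither passed (edgeR, adjusted p = 0.0538 and 0.239). In B-like cells, Treml1 rose by 1.22 ± 0.21 (SE, edgeR adjusted p = 0.00804), Clec1b by 1.12 ± 0.19, Pf4, platelet factor 4, by 1.01 ± 0.18 and Gp9 by 0.71 ± 0.16. The median log2 fold change over the platelet list was 0.85 in Cd8b-low T-like, 0.89 in Cd8b-high T-like, 0.88 in regulatory T-like, 1.01 in B-like, 0.66 in NK-like, 0.75 in non-classical monocyte-like and 1.40 in erythroid-like cells. Classical monocyte-like cells differed: their median was -0.19 and none of 10 members passed. The platelet list passed camera in each of these 8 classes, downward in the classical monocyte-like cells (adjusted p = 0.00980) and upward in the others, where adjusted p was lowest in Cd8b-high T-like cells at 2.5e-05; with an estimated correlation adjusted p was 0.70 in 7 of the 8 and 0.713 in classical monocyte-like cells.

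**Figure D3:**
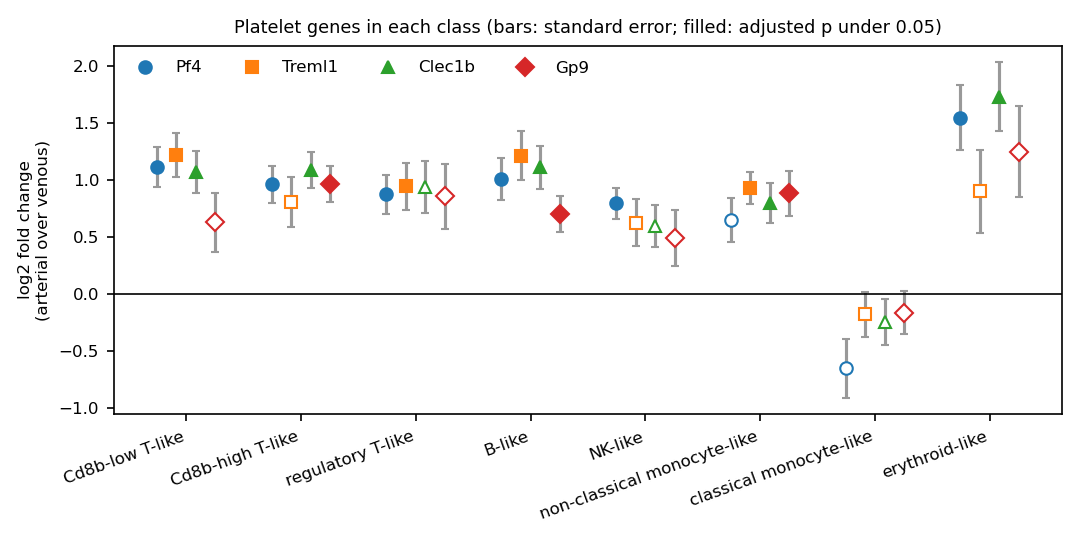
Log2 fold change (arterial over venous, y axis) of Pf4, Treml1, Clec1b and Gp9 in 8 classes (x axis); bars are standard errors, filled symbols passed adjusted p 0.05 (edgeR) and open symbols did not. The symbols lie above 0 in 7 classes, with Pf4 at 1.55 in erythroid-like cells, and below 0 in classical monocyte-like cells, with Pf4 at -0.65.

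Some genes were called in many classes. Over the 7 lymphoid and monocyte classes, 1063 genes were called in at least 1 class, 332 in at least 2 and 74 in at least 4, and 14 were called in both directions. The 5 genes called in all 7, each time higher in arterial blood, were Birc3, Ell2, Gna13, Slc7a1 and Zc3h12a, an RNase that degrades inflammatory transcripts; these were picked after their values were seen. The clock gene Nr1d2 was higher in 6 of the 7 classes, and Cxcr4, Foxo1 and Bhlhe40 in 5. The glucocorticoid response list, in which Sgk1, Klf9 and Cxcr4 recur, passed camera in 6 of the 7 classes, with a median of 0.37 in classical monocyte-like and 0.09 in Cd8b-low T-like cells and adjusted p of 0.70 with an estimated correlation in each. In all, 45 of 277 tests of lists passed camera with the preset correlation of 0.01, 0 passed with an estimated correlation (lowest adjusted p = 0.70), and 0 passed fry (lowest adjusted p = 0.0810). With the vessels of some rats exchanged, between 12 and 39 tests still passed camera with the preset correlation. A pass of camera alone therefore does not set a list apart as a difference between the vessels. Beside the platelet list in Cd8b-low T-like cells, the haemoglobin list also passed camera there (median 0.43, adjusted p = 0.0194; adjusted p = 0.787 with an estimated correlation).

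Every one of these gene counts depended on the pairing. With no rat block, edgeR called 0 genes in each of the 7 classes, with between 89 and 176 at an unadjusted p under 0.05. Leaving out rat 1, 2, 3, 4 or 5 gave 54, 56, 41, 197 and 893 genes in Cd8b-low T-like cells and 36, 16, 22, 76 and 688 in Cd8b-high T-like cells. In the same order it gave 9, 16, 22, 93 and 314 in regulatory T-like, 159, 129, 167, 420 and 1261 in B-like and 29, 58, 4, 41 and 170 in NK-like cells. It gave 35, 28, 26, 153 and 360 in non-classical and 85, 87, 191, 373 and 570 in classical monocyte-like cells. Within rats 1 to 3 the counts over the 7 classes, in the order just given, were 1312, 1190, 357, 1512, 166, 541 and 773, and within rats 4 and 5 they were 0, 0, 0, 0, 34, 55 and 11 (edgeR, between 314 and 832 at an unadjusted p under 0.05). In rats 4 and 5 most calls in non-classical (43 of 55) and classical monocyte-like cells (10 of 11) were lower in arterial blood, unlike those of the 5 pairs. Of the 346 genes called in classical monocyte-like cells, 264 had the same direction within rats 4 and 5, against 532 of 554 in B-like cells; both counts are favoured by the choice of the genes on the same pairs.

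The rarer classes gave fewer calls. Erythroid-like barcodes had 15 genes higher and 1 lower of 1985 tested (edgeR), led by the platelet genes Clec1b (1.73 ± 0.30 SE) and Pf4 (1.55 ± 0.29) with Tsc22d1 (1.62) and with Npy (1.57) and Pla2g2a (1.51), which also lead the platelet-like cluster. Leaving out rat 1, 2, 3, 4 or 5 gave 13, 10, 0, 163 and 7 genes there. Plasmacytoid dendritic-like cells, compared in 3 pairs, had 2 genes lower, Mcpt9, a mast cell protease gene, and Slpi, a secreted protease inhibitor (-3.67 ± 0.53). Without rat 1, 2 or 3, which leaves 2 pairs, 12, 9 and 20 genes passed in this class, and DESeq2 called 0. Mcpt9 had 0 UMIs in the arterial and 394 in the venous sums, which against a floor of 3 counts over the group is at least 64.3-fold lower. Slpi is also a leading gene of the neutrophil-like cluster. RNA or cells of the mast cell or neutrophil lineage are not excluded as the source of these 2 genes. No gene passed in neutrophil-like cells (3 pairs; edgeR, 33 genes at an unadjusted p under 0.05), platelet-like barcodes (116 unadjusted) or proliferating cells (673 unadjusted), and DESeq2 also called 0 genes in each. In platelet-like barcodes the mitochondrially encoded genes had a median of 0.59, with 10 of 12 higher adjusted over the list alone (camera adjusted p = 8.36e-07; adjusted p = 0.70 with an estimated correlation), and none passed over all genes tested.

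Whether the vessel acted differently on different classes was tested as an interaction. Monocyte-like cells here pool the classical and non-classical classes, and T-like cells pool all T-like classes. With the library as the block, no gene had a vessel effect that differed between monocyte-like and T-like cells among 13552 tested (edgeR, 436 genes at an unadjusted p under 0.05 and 0 calls with DESeq2's size factors too) or between B-like and T-like cells among 13537 (412 unadjusted). In simulated data this fit recovered 48% of genes planted with a log2 fold of 1 and 7% of those with 0.5 in the first comparison, and 63% and 26% in the second. When blocks for each class within each rat were added, a choice made after the data were seen, 437 and 353 genes passed.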

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

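The mononuclear denominator and the stricter cell filter were planned as alternatives, but their use as tests of an explanation was written down only after the results were seen for the NK-like denominator and for both tests of the non-classical monocyte-like share. The test of handling was chosen only after the results it bears on were seen, and so were the comparisons within sets of rats and the class-by-rat blocks. The other tests below were written down before their results were seen, but on patterns already noticed in the same data.

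Some platelet genes were higher in arterial T-like, B-like, NK-like, non-classical monocyte-like and erythroid-like cells, from 1 of 6 tested in NK-like to 4 of 7 in B-like cells, with medians of the list from 0.66 to 1.40 on the log2 scale. The list passed camera with a preset correlation in each, but not with an estimated correlation (adjusted p = 0.70), and fry called none. After thinning, 3 of the 4 platelet genes called in B-like cells were still called, with a median of 1.09 against 1.06 before. This argues against the total counts of the sums as the whole cause of the calls. Thinning leaves the expected fold unchanged, so an effect of depth per cell was not tested. RNA of platelets, free or from platelets that stuck to other cells, may be the source. Over 12 platelet genes, the profile of each of 5 lymphoid classes followed that of the platelet-like cluster. The lowest Pearson r across genes was 0.878. These profiles pooled both vessels, so they bear on the presence of platelet RNA and not on the difference between the vessels. Monocyte-like and erythroid-like classes were not part of that test. The unnamed cluster 10, which joins T and platelet markers, was also higher in arterial blood in 5 of 5 pairs (1.24 ± 0.34, edgeR adjusted p = 0.0538). Classical monocyte-like cells, with a median of -0.19, depart from what an even film of free RNA would give, and this part stays open. Whether more platelets in arterial blood or their activation during the draw stand behind it was not tested.

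Targets of NF-kB were higher in arterial classical monocyte-like cells (median 0.57 over 20 members). Neutrophil RNA or neutrophils among these cells are argued against, since the median of 8 neutrophil genes was -0.0167. After thinning, 8 of the 13 called members were still called, which argues against the total counts of the sums as the whole cause of the calls. Of the 13, 11 kept their direction and the others were no longer tested. The median went from 0.84 to 0.72, the latter over those still tested. Thinning leaves the expected fold unchanged, so an effect of depth per cell was not tested. A difference in handling between the draws cannot be told apart from the vessel, here or in any other class. The order and time of the draws are not given in the labels. In classical monocyte-like cells, 6 immediate early genes, which respond to handling, were called. An effect of the vessel itself stays open as an untested hypothesis, and other ways to split the same libraries gave many genes in this class, as given at the end of this part.

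NK-like and non-classical monocyte-like cells were less frequent in arterial blood (-0.67 ± 0.17 and -0.53 ± 0.13). More erythroid-like and platelet-like barcodes in the denominator are argued against as the whole cause, since with mononuclear cells alone the values were -0.582 ± 0.16 and -0.451 ± 0.13. Under a stricter cell filter they were -0.449 ± 0.13 and -0.228 ± 0.11, over 2 standard errors below 0. That filter cuts at 5% mitochondrial UMIs, near the library medians of 4.74% to 5.27% in rats 1 to 3. It thus also removes many typical cells of those rats, and cannot decide how much of the difference cells of low quality account for. Both calls ended under that filter (edgeR, adjusted p = 0.0907 and 0.232): the differences shrank by more than their standard errors did, and what the adjustment over the other classes added was not separated. A difference in the release or trapping of these cells between the vessels stays open and was not tested.

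Among 236 groups of 5 libraries that were examined, 9 had 1 library far from the other 4 by Dixon's ratio, and chance gives about 1 in 20. The venous library of rat 2 had 2.30% NK-like cells against 5.06% to 5.86% in the others (ratio 0.775). The venous library of rat 4 had 9.17% erythroid-like barcodes against 0.215% to 2.08% (0.792) and a median of 5047 UMIs per cell against 3963 to 4189 (0.792). The venous library of rat 3 had 0.900% neutrophil-like cells against at most 0.257% (0.714). In sums of all cells, log2 CPM of Sytl4 was -4.25 in the venous library of rat 5 against -2.33 to -1.60 (0.727), that of Kir3dl1 was -0.38 in the venous library of rat 2 against 0.77 to 0.99 (0.840), and that of Kcnj1 was -1.97 in the arterial library of rat 4 against -0.87 to -0.63 (0.820). Ccl5 in Cd8b-high T-like cells stood at 10.71 in the venous library of rat 2 against 8.33 to 8.98 (0.726), and Slc40a1 in B-like cells at -1.99 in the venous library of rat 5 against 1.06 to 2.26 (0.718).

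With class-by-rat blocks, 437 genes had a vessel effect that differed between monocyte-like and T-like cells and 353 one that differed between B-like and T-like cells (edgeR), against 0 and 0 with the library alone as the block. In simulated data with those blocks, between 6.11% and 15.1% of calls were false in the first comparison and between 3.6% and 11.1% in the second.

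The counts of changed genes were set against the 16 splits that part all 5 pairs, the real one included, or 4 splits where 3 pairs were held. Neither number can give a share under 0.05. The real count and the highest of the other splits were 982 and 1 for all cells, 310 and 3 for Cd8b-low T-like, 170 and 2 for Cd8b-high T-like, 93 and 9 for regulatory T-like, 554 and 0 for B-like, 81 and 2 for NK-like, 114 and 15 for non-classical monocyte-like and 346 and 263 for classical monocyte-like cells. For erythroid-like barcodes they were 16 and 3, for plasmacytoid dendritic-like cells 2 and 0, for neutrophil-like cells 0 and 2, for platelet-like barcodes 0 and 1 and for proliferating cells 0 and 16. They were 4 and 2 for classes with a changed share, 2 and 1 for clusters, 45 and 39 for gene lists and 0 and 0 for both interactions. In all cells, in the 8 classes with genes called in 5 pairs, in plasmacytoid dendritic-like cells and for classes, clusters and lists, 1 split reached the real count, the real one itself. For neutrophil-like cells 4 of 4 splits did, and for platelet-like barcodes, proliferating cells and both interactions 16 of 16. The 263 genes came from the split with the vessels of rat 5 exchanged. Of 40 drawn splits that need not part the pairs, the highest gave 599 genes in all cells and the median was 0. The rat block was kept in these fits, so only the parted pairs bear on a count. The split with 599 genes parted 3 pairs, and the cause of its count was not tested.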

How the results depend on the processing

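The comparisons within sets of rats, without platelet cluster genes, with class-by-rat blocks and with erythroid barcodes counted over all deposited barcodes were chosen after seeing the data; the others were planned. The 4 changed classes kept their direction under every alternative run, but of these calls only that of platelet-like barcodes held without the rat block. At other resolutions clusters were named anew, so classes of the same name did not hold the same cells. The sets of rats and the fits with a rat left out have fewer pairs, and thinned sums fewer counts. Fewer pairs do not explain counts that rose, such as those without rat 5 or within rats 1 to 3, and the cause of these and of the other changes was not tested. Thinned sums left few genes tested in rarer classes: 7 in neutrophil-like, 277 in erythroid-like, 590 in platelet-like and 821 in plasmacytoid dendritic-like cells.

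Without the rat block, which drops the pairing, the log2 fold change of the share was -0.65 for NK-like, -0.55 for non-classical monocyte-like and 1.03 for erythroid-like cells, none of them called, and it reversed to -0.024 for classical monocyte-like and -0.052 for proliferating cells. Then 1 class, 1 cluster and 23 lists passed, and 0 genes passed in all cells and in each of the 9 classes that had calls (edgeR, between 8 and 248 at an unadjusted p under 0.05). No other call changed without the block.

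Under the stricter cell filter, which removes many cells of rats 1 to 3, the shares were -0.45 for NK-like, -0.23 for non-classical monocyte-like, 0.26 for erythroid-like and 1.04 for platelet-like cells, no longer called, and -0.46 for B-like cells, now called, with 1 class and 5 clusters passing; the log2 ratio of lymphocytes to monocytes differed by 0.072 in place of 0.36 (0.24 to 0.41 without single rats). A different erythroid measure was the percent of all deposited barcodes with at least 50% haemoglobin UMIs. Its mean paired log2 difference was 0.79 (exact sign-flip permutation p = 0.063), beside edgeR's 1.17 for the erythroid-like class. TMM factors over the counts of cells gave -0.70 for NK-like and -0.56 for non-classical monocyte-like cells, not called, and 2 classes. A resolution of 0.5 gave -0.57 for NK-like and 0.67 for erythroid-like cells, not called, and 2 classes. Clusters were named anew there, and the NK-like class took in a cluster of 1140 cells with Cd8b in 46.0% of them. No cluster of mixed erythroid markers stayed unnamed at that resolution. Limma on shares called B-like cells at -0.52. With mononuclear cells as the denominator, Cd8b-high and Cd8b-low T-like cells were called at 0.26 and 0.28. With doublet calls kept, proliferating cells reversed to -0.053 and unnamed cells to -0.065, and 7 clusters passed. The ratio of Cd8b-low and regulatory to Cd8b-high T-like cells then differed by 0.14, and 13 genes were called in plasmacytoid dendritic-like and 25 in neutrophil-like cells. At a resolution of 2 proliferating cells reversed to -0.0055. There a cluster of 1163 cells led by Cd8a and Cd8b, with Cd8b in 71.9% of them, was named platelet-like.

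Within rats 1 to 3 the shares of NK-like (-0.91), erythroid-like (1.43) and non-classical monocyte-like cells (-0.66) were not called, 1 class passed, and classical monocyte-like (-0.085) and proliferating cells (-0.24) reversed. Genes called were 1312 in Cd8b-low T-like, 1190 in Cd8b-high T-like, 357 in regulatory T-like, 1512 in B-like, 166 in NK-like, 541 in non-classical monocyte-like, 773 in classical monocyte-like, 39 in erythroid-like and 34 in proliferating cells. Within rats 4 and 5, NK-like (-0.30) and non-classical monocyte-like cells (-0.35) were not called, B-like cells were (-0.70), and plasmacytoid dendritic-like (0.53) and unnamed cells (-0.25) reversed. Genes called were 0 in all, Cd8b-low T-like, Cd8b-high T-like, regulatory T-like, B-like and erythroid-like cells, 34 in NK-like, 55 in non-classical monocyte-like (12 higher, 43 lower), 11 in classical monocyte-like (1 higher, 10 lower) and 28 in proliferating cells. Treml1 in regulatory T-like cells (-0.051), and Egln1 (-0.13), Txnrd1 (-0.0088) and Relb (-0.16) in classical monocyte-like cells reversed there.

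DESeq2's Wald test called 1625 genes in all, 271 in Cd8b-high T-like, 52 in regulatory T-like, 52 in NK-like, 195 in classical monocyte-like, 0 in plasmacytoid dendritic-like and 32 in erythroid-like cells, and with DESeq2's size factors edgeR called 10 in erythroid-like cells. Library sizes without haemoglobin, platelet, neutrophil and immunoglobulin genes gave 410 higher and 608 lower genes in all cells in place of 538 and 444. With no filter on low counts the numbers were 633 in Cd8b-low T-like, 637 in Cd8b-high T-like, 387 in regulatory T-like, 1140 in B-like, 351 in NK-like, 404 in non-classical monocyte-like, 565 in classical monocyte-like, 46 in plasmacytoid dendritic-like, 3 in neutrophil-like, 41 in platelet-like, 27 in erythroid-like and 153 in proliferating cells. Thinned sums gave 338 in B-like, 63 in non-classical monocyte-like, 44 in classical monocyte-like, 5 in plasmacytoid dendritic-like and 4 in erythroid-like cells. Without platelet cluster genes, 7 were called in erythroid-like cells, 3 of them among the 16 of the main fit. An estimated correlation and fry called 0 lists. Class-by-rat blocks gave 437 genes for monocyte-like and 353 for B-like against T-like cells.

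Leaving out each rat in turn gave -0.78 to -0.54 for NK-like, -0.58 to -0.41 for non-classical monocyte-like, 0.98 to 1.29 for erythroid-like, -1.28 to 0.50 for neutrophil-like and -0.022 to 0.40 for proliferating cells, with 1 to 4 classes and 0 to 3 clusters called. The counts of genes ran from 21 to 1272 in all, 41 to 893 in Cd8b-low T-like, 16 to 688 in Cd8b-high T-like, 9 to 314 in regulatory T-like, 129 to 1261 in B-like, 4 to 170 in NK-like, 26 to 360 in non-classical monocyte-like, 85 to 570 in classical monocyte-like, 9 to 20 in plasmacytoid dendritic-like, 0 to 11 in platelet-like, 0 to 163 in erythroid-like and 0 to 1 in proliferating cells. Over all alternatives, not only the fits with a rat left out, single genes, lists and the share of unnamed cells were tallied together. They kept their direction and their side of the threshold in 3243 cases, lost the call in 1778, gained it in 20 and reversed in 6.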

Other observations

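The genes named in the next paragraph were picked after their values were seen, and the class-by-rat blocks were chosen after seeing the data; the test of cluster 20 was written down before its result was seen.

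With class-by-rat blocks, genes whose log2 fold change was higher in monocyte-like than in T-like cells included Id3 (difference in log2 fold change 1.5 ± 0.14 SE, edgeR adjusted p = 5.18e-07), the transcription factor gene Runx3 (0.82 ± 0.08), the phosphatase gene Dusp2 (0.81 ± 0.10) and Pfkfb3 (0.50 ± 0.06), a driver of glycolysis. The log2 fold change was lower in monocyte-like cells for Trem1 (-0.93 ± 0.08, edgeR adjusted p = 3.81e-07), Trem3 (-1.20 ± 0.14), the neuropeptide gene Npy (-0.87 ± 0.08), Pf4 (-1.03 ± 0.12) and the interferon gamma receptor genes Ifngr1 (-0.38 ± 0.04) and Ifngr2 (-0.74 ± 0.08). A lower value need not be a smaller rise: Pf4 was at -0.65 in classical and 0.65 in non-classical monocyte-like cells. Ccl5 differed by 1.13 ± 0.13. Of the 437 genes, 197 had a positive and 240 a negative difference. Npy and Pf4 are also leading genes of the platelet-like cluster. The ratio of classical to non-classical monocyte-like cells, pooled here, was higher in arterial blood by 0.68 ± 0.38 (SD, n = 5) on the log2 scale. These differences may therefore carry part of that shift.

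Between B-like and T-like cells, the immediate early genes Fos (difference 1.02 ± 0.07, edgeR adjusted p = 8.97e-08) and Fosb (1.15 ± 0.13) had the higher log2 fold change in B-like cells. So did S100a4 (1.39 ± 0.13), Zfp36 (0.39 ± 0.04), an RNA-binding regulator of cytokine transcripts, and the haemoglobin gene Hba-a3 (0.84 ± 0.09). Such a difference can include a fall in T-like cells. Of the 353 genes, 227 had a positive difference. None of these differences was called in the fit with the library alone as the block.

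Ccl5 and Zeb2 were lower in arterial Cd8b-high T-like cells. A candidate explanation is a smaller share of cluster 20, led by Ccl5, Gzmm and Gzmk, among T-like cells. That share was lower in the arterial library in 5 of 5 pairs, at 0.945% ± 0.440 (SD, n = 5) against 1.45% ± 0.557 (exact sign-flip permutation p = 0.063, the smallest that 5 pairs allow). Since Ccl5 also defines the cluster, composition and expression per cell cannot be separated by this test.

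Plasmacytoid dendritic-like cells had MHC class II genes with a median of -0.42, with 8 of 12 lower adjusted over the list alone and none over all genes tested (camera adjusted p = 0.00130; adjusted p = 0.70 with an estimated correlation). Oxidative phosphorylation genes had medians of -0.08 in Cd8b-high T-like and -0.07 in B-like cells (camera adjusted p = 0.0117 and 0.0190; adjusted p = 0.70 with an estimated correlation for both).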
